A study of Mus musculus with 3 samples.

How the data were processed

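Lung cells of C57BL/6J male mice were measured by droplet single-cell RNA sequencing (10x Genomics Chromium Next GEM 3' kit, v3.1 per the labels) in 3 libraries, 1 each for NVC, ARDS and Bifidus. The submitters' processing notes name Cell Ranger, without a version, Seurat 4.1.1 and the mouse build mm10. The deposited values are raw UMI counts per gene and barcode for all barcodes, without a cell filter; the authors' cell calls and cell types were not used here. The files hold 689571, 709788 and 697491 barcodes with 48357886, 73287246 and 70852812 UMIs for NVC, ARDS and Bifidus. They list the same gene IDs in the same order; 78 IDs share their symbol with another, and where a list names such a symbol its first ID was used. Gene coordinates come from the GENCODE annotation of GRCm38.

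Barcodes with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs were kept. Scrublet found no doublets at its own threshold, so the roughly 6% of cells with the highest scores were left out (674, 673 and 563 cells). This left 10269, 10493 and 8634 cells with 35003365, 54589488 and 57697971 UMIs. Their median mitochondrial share was 2.68%, 1.26% and 1.23%.

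Cells of the 3 libraries were clustered together in scanpy 1.11.5 with leidenalg 0.10.2: counts scaled to 10000, 3000 variable genes chosen within libraries, without Thbs1, 30 principal components, 15 neighbours, resolution 1.5 and seed 0. Each of the 59 clusters took the name, among 25 cell types with fixed markers, whose markers were highest against the other clusters, with at least 3 markers 2 times higher and seen in 20% of its cells; 18 classes were found. A cluster whose leading genes pointed to another class, or held no marker, stayed unnamed. Clusters shallower than their library's median whose profile correlated with free RNA at 0.85 or more were also left unnamed, a rule chosen after the data were seen. No integration across libraries was applied, so clusters can separate by library. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and anndata 0.12.19.

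Free RNA was profiled in barcodes of 10 to 100 UMIs. Its share in cells, from Sftpc, Scgb1a1 and S100a9 in T and B cells, was 4.88% in NVC, 3.38% in ARDS and 2.72% in Bifidus. It was not subtracted from the values reported, and subtraction was an alternative.

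Each comparison sets 1 library against 1, and cells are not replicates, so no test was run and no p-value is given. Shares have exact Clopper-Pearson intervals, sums of UMIs exact Poisson intervals, and ratios of sums or of shares exact conditional binomial intervals, each at 95%. A gene at 0 UMIs was set to a floor of 3 UMIs for a bound. Levels are CPM over the summed UMIs of a class with at least 100 cells in each library.

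For 20 gene lists the median log2 ratio, with 5 CPM added, was taken over members with at least 10 UMIs in the pair of libraries, with its percentile among 10000 random lists matched on expression. The lists for epithelial junctions, surfactant and transitional epithelium gave no value, because AT1, AT2 and club cells were under 100 in the ARDS and Bifidus libraries. The genes named were fixed by rule before the data were examined. In the 5 classes with the most cells in the smaller library, these were the 3 highest and 3 lowest ratios among genes with at least 100 CPM and 30 UMIs, at least 5 times the free RNA level, a ratio of at least 2 and an interval beyond 1.5. Mitochondrial, ribosomal, haemoglobin, receptor variable and unnamed genes were left out of the ranking. Thbs1, Cd47 and Cd36 were to be named in every class; for some classes only the range of their ratios is given, or none, a choice made after the values were seen. Of each list the rule took up to 3 members with the largest ratio, at 50 CPM and 30 UMIs or more. The comparisons, lists, thresholds and most alternatives were likewise set beforehand. Those alternatives were a floor of 1000 UMIs or a floor per library, 5% mitochondrial UMIs, no doublets left out, resolution 0.8, seed 1 and each library clustered alone. For levels they were the mean of cells, the median of ratios, free RNA taken off, 1 CPM added, members with 1 UMI, and unthinned cells for the share with Thbs1. 3 choices were added later: naming without the free RNA rule, leaving out small clusters of 1 library, and counting cluster 9 with the classical monocytes. Also chosen after the values were seen were Thbs1 in the NVC classical monocytes, monocytes and interstitial macrophages as 1 set, the genes of clusters 9 and 11, the heat shock genes of lymphocytes and the levels within clusters that hold both libraries.

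The procedure was tested on simulated data drawn from the mean levels and totals of these libraries. The counts held counting error only, as the intervals assume, and no free RNA. The test thus checks the calculation. It does not cover variation between cells, animals or libraries, or the free RNA bound of the naming rule. For Bifidus against ARDS in neutrophils (1085 genes) the 95% intervals held the true ratio for 95.6% of genes. All planted changes of 4 times passed the naming rule, 51% of those of 2 times did, and no unchanged gene did. For ARDS against NVC in T cells (1024 genes) the values were 95.5%, 96%, 42% and 0%. Random lists without a change lay beyond the outer percentiles in 1.5% and 0% of 200 cases.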

Results

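Mouse lung cells (C57BL/6J males) were profiled by droplet single-cell RNA sequencing in 3 libraries, named NVC, ARDS and Bifidus, with 1 library per group. The series concerns thrombospondin-1 and a Bifidobacterium feed in a mouse model of acute lung injury; ARDS stands for acute respiratory distress syndrome. The labels do not spell out NVC, do not say whether the Bifidus lungs were injured, and do not say whether a library holds 1 mouse or a pool. The NVC library held 48357886 UMIs (unique molecular identifiers), the ARDS library 73287246 and the Bifidus library 70852812. After filtering, 10269 NVC cells, 10493 ARDS cells and 8634 Bifidus cells were kept, with medians of 2308, 2946 and 4174 UMIs per cell. With 1 library per group no difference below has a replicate check, and an effect of the group cannot be separated from that of the animal or of the preparation. Intervals in brackets are 95% intervals and cover counting error only.

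Cells were sorted into 18 classes by marker genes, and each class name below means cells that resemble that type (neutrophil-like, and so on). The unnamed share was 7.47% of NVC cells, 9.98% of ARDS cells and 14.4% of Bifidus cells. Clusters left unnamed only because their profile was close to free RNA made up 1.97%, 1.90% and 0.0579% of the libraries and are part of the unnamed share. Clusters 31, 42 and 46 (186, 113 and 82 ARDS cells) and 44 (103 NVC cells) were also that close to free RNA. They were unnamed for their leading genes first and are not in these percentages. Levels are given in CPM, the UMIs of a gene relative to all UMIs summed over the cells of a class in a library.

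**Figure D1:**
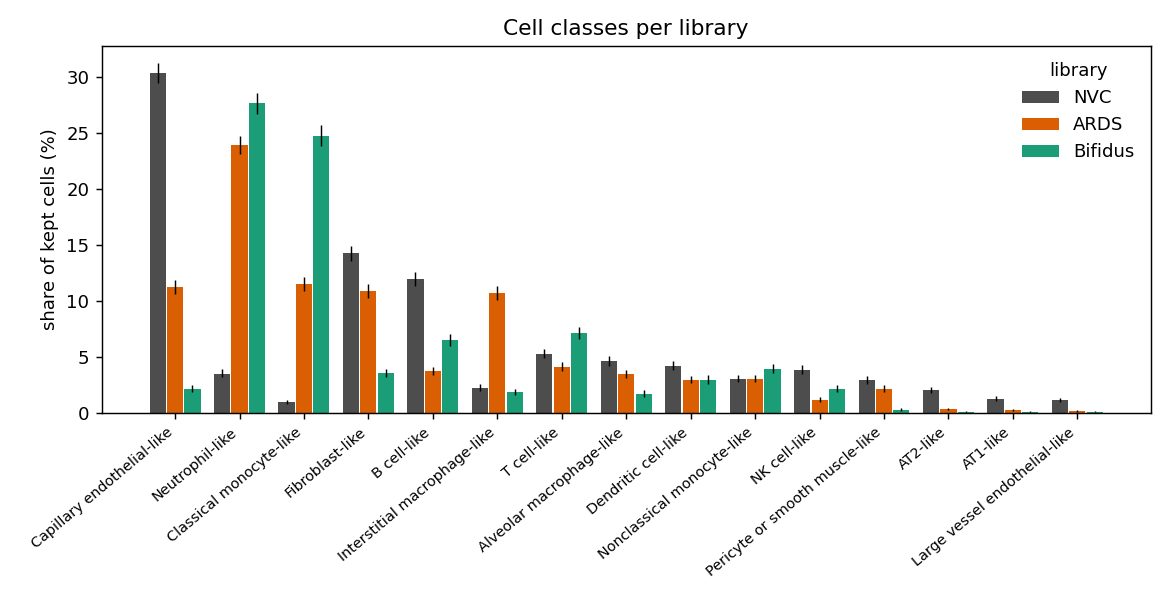
Share of kept cells (%) in each class with at least 100 cells in any library, for the NVC, ARDS and Bifidus libraries; error bars are exact 95% binomial intervals. Neutrophils were 3.50%, 23.9% and 27.6% of cells and capillary endothelial cells 30.3%, 11.2% and 2.12%.

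ARDS against NVC asks how the lung labelled ARDS differed from the NVC lung. Neutrophils were 23.9% of ARDS cells [23.1 to 24.7] and 3.50% of NVC cells [3.15 to 3.87], a share 6.84 times higher [6.12 to 7.66]. Classical monocytes made up 11.5% against 0.945%, and interstitial macrophages 10.7% against 2.25%. Capillary endothelial cells were 2.70 times lower in share [2.53 to 2.89] (a ratio of 0.370, and 0.191 with a floor per library), AT2 cells 6.13 times lower [4.27 to 9.04] (a ratio of 0.163, and 0.276 without the small clusters of 1 library) and AT1 cells 5.53 times lower [3.56 to 8.95] (a ratio of 0.181, and 0.304 with a floor per library). B cells were 3.20 times lower [2.86 to 3.60] (a ratio of 0.312, from 0.150 over the alternatives) and NK cells 3.34 times lower [2.71 to 4.12], whereas fibroblasts (1.31 times lower) and T cells (1.28 times lower) differed less. Shares are of sampled cells, so a larger class lowers all others: within non-immune cells alone, AT2 cells were 2.94 times lower and fibroblasts 1.59 times higher. The size of these ratios depends on the clustering: with each library clustered alone the share ratio was 3.32 for neutrophils, 1.21 for interstitial macrophages (4.75 with the libraries together) and 0.461 for AT2 cells (0.163), and with seed 1 it was 5.63 for classical monocytes (12.2).

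Different clusters filled several classes in these libraries. Interstitial macrophages came from cluster 26 in the NVC library (99.6%) and from cluster 7, led by Arg1, in the ARDS library (95.5%). NVC neutrophils were mostly cluster 2 (78.6%), and ARDS neutrophils were clusters 3 and 6 (51.0% and 45.9%). Alveolar macrophages (cluster 17 against 24), capillary endothelial cells (4 against 10) and fibroblasts (15 against 16) were split likewise. A cluster mostly of 1 library may be that library rather than a cell type, so the values per class below compare class members that cluster apart.

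Interferon-stimulated genes were higher in ARDS cells in each of the 11 classes compared, with list medians (log2 ratio) from 1.10 in NK cells to 3.62 in interstitial macrophages. Each of those medians had percentile 100 among 10000 random lists matched on expression. Gbp2 stood at 1577 CPM in ARDS neutrophils against 52.4 CPM in NVC neutrophils, and Ifi47 at 764 against 9.03 CPM. In dendritic cells Ifi47 was 121 times higher [69.1 to 235]. In T cells Ifit1 reached 100.2 CPM against 1.06 CPM (180 and 2 UMIs, ratio 94.9 [25.9 to 789]), and in B cells Irgm1 was 19.5 times higher [12.4 to 32.0].

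Cytokine and chemokine genes were higher as well in the 4 myeloid classes compared. Their list median was 1.84 in neutrophils, 1.89 in nonclassical monocytes (1.04 to 2.67 over the alternatives), 2.96 in alveolar macrophages and 1.17 in interstitial macrophages. Cxcl10, a chemokine for T cells, was 3769 CPM in ARDS and 14.5 CPM in NVC neutrophils, Il1a 1526 against 9.03 CPM, and Tnf 1472 against 32.5 CPM. In alveolar macrophages Cxcl3 was 109 times higher [86.3 to 139] and Lcn2, which binds bacterial siderophores, 1424 against 1.12 CPM (3 NVC UMIs, ratio 1270 [434 to 6161]). NF-kB feedback and target genes had medians of 2.33 in neutrophils, 1.76 in alveolar macrophages and 1.92 in capillary endothelial cells, but 0.22 in interstitial macrophages (percentile 59.3). Icam1 in neutrophils was 24.6 times higher [17.9 to 34.8]. Inflammasome genes had medians from 0.40 in neutrophils to 0.72 in nonclassical monocytes.

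Clearance and alternative activation genes were lower in ARDS interstitial macrophages (median -1.72) and alveolar macrophages (-0.41). Retnla stood at 3.23 CPM in ARDS and 2337 CPM in NVC interstitial macrophages, and Gas6 at 3.64 against 161 CPM, while Arg1 (326 CPM against 0) was at least 155-fold higher. Arg1 and Gas6 were among the markers that named this class. Its ARDS cells were mostly cluster 7 (95.5%), led by Arg1, and its NVC cells cluster 26 (99.6%). Within 1 cluster these genes were not compared, so a change of level cannot be told apart from the joining of different clusters. Glycolysis and hypoxia genes were higher in ARDS interstitial macrophages (median 1.48, Pkm 6.97 times [6.20 to 7.87]). MHC class II genes were lower in interstitial macrophages (-1.37), capillary endothelial cells (-1.32), dendritic cells (-0.75) and B cells (-0.65) and higher in alveolar macrophages (0.51). The granule and migration list was lower in ARDS neutrophils (-0.86), with Camp at 139 against 5243 CPM and Elane at 0.316 against 293 CPM (2 ARDS UMIs, 927 times lower [253 to 7721]). Cluster 53, of 60 NVC cells and led by Camp, is in this class: without the small clusters of 1 library the median was -0.77, and with scaling by the median of ratios -0.24.

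In fibroblasts Saa3, a serum amyloid gene, stood at 28221 CPM against 21.3 CPM, Lcn2 at 9538 against 5.29 CPM, and Saa1 at 367 against 0.171 CPM (1 UMI, ratio 2154 [386 to 85104]). Stbd1 (16.1 times), Lrat (15.5 times) and Gas1 (13.4 times) were lower. Timp1 was 33.6 times higher in fibroblasts [31.7 to 35.6] and 18.3 times in pericytes or smooth muscle cells, although the extracellular matrix list as a whole had medians of -0.30 (0.02 with each cell weighted alike) and 0.15 there. In capillary endothelial cells Lcn2 was 743 times higher [340 to 2027], and AA467197 (195 against 0.552 CPM) and Saa3 (605 against 0.138 CPM; 1 NVC UMI, ratio 4382 [785 to 173178]) were higher too; free RNA would give 117.5 CPM of this Saa3. Cyp1a1 was at 0.788 against 670.4 CPM (2 UMIs, 850.4 times lower [235 to 7024]), Wfdc1 18.3 times lower and Car14 15.9 times lower. The endothelial activation list had a median of 1.78 and the endothelial junction list one of -0.64, with Cldn5, a tight junction gene, at 1777 against 4350 CPM. Antioxidant and metallothionein genes had a median of 1.28 in capillary endothelial cells (Mt2 430.4 against 3.59 CPM), of -0.63 in dendritic cells and of -0.78 in neutrophils (percentile 3.91; -0.80 to -0.15 over the alternatives).

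Lymphocytes differed in activation and antibody genes. T and NK cell activation genes had medians of 0.82 in T cells and 0.69 in NK cells; Ifng was 5417 CPM in ARDS and 399 CPM in NVC NK cells. Ccl3 in T cells was 8.26 times higher [4.51 to 16.6], a direction that did not hold once free RNA was taken off. H2-Aa, H2-Eb1 and H2-Ab1 stood at 302, 263 and 249 CPM in NVC T cells, where free RNA gives 56.4, 45.8 and 46.5 CPM, and in ARDS T cells near the level that free RNA gives. Jchain and Igha, antibody genes, had 0 UMIs in the 391 ARDS B cells, at least 373-fold and 217-fold lower than in NVC B cells, and the B cell list had a median of -0.66. Both genes were among the plasma cell markers, and no cluster was named as plasma cells. Any plasma cells within the B cell class were therefore not told apart from a change of level in B cells. Cell cycle genes lay among the lowest 2.5% of random lists in 7 of the 11 classes, with -1.77 in NK cells (-2.21 to -0.97 over the alternatives), -1.61 in neutrophils (-2.70 to -0.86) and -0.96 in capillary endothelial cells (-1.32 to -0.48), and had a median of 0.53 in fibroblasts. Immediate early and heat shock genes were lower in pericytes or smooth muscle cells (-1.11, -1.94 to -0.92 over the alternatives), capillary endothelial cells (-1.004) and fibroblasts (-0.99) and higher in T cells (0.33) and B cells (0.28). Zbp1 (8.35 times) and Ifi47 (8.08 times) in B cells, Ifit3 (71.3 times [24.1 to 349]) and Isg20 (16.3 times) in T cells, and Ly6i (425 times [76.0 to 16793]) and Serpina3g (412 times [114 to 3408]) in alveolar macrophages were the other highest ratios. Ly6c2 in B cells (10.0 times) and Lpin1, Fosb and Fabp1 in alveolar macrophages (13.2, 10.8 and 10.2 times) were the other lowest ones.

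Thbs1 (ENSMUSG00000040152) encodes thrombospondin-1, a secreted matrix protein, and lies on chromosome 2 of GRCm38 from 118111876 to 118127133 on the forward strand. Over all cells it was 864 CPM in the ARDS and 592 CPM in the NVC library, 1.46 times higher [1.44 to 1.48]. The direction differed between classes. Thbs1 was lower in ARDS neutrophils (2316 against 4662 CPM, 2.01 times; ratio 0.497, and 0.769 with the median of ratios) and nonclassical monocytes (560.0 against 1278 CPM, 2.28 times), in which the ratio of 0.438 ran from 0.221 with a floor per library to 0.915 with seed 1. The nonclassical class, cluster 11, also carried classical monocyte genes, which differed between libraries in no common direction. In its NVC, ARDS and Bifidus cells Ccr2 stood at 164, 636 and 549 CPM, Vcan at 54.1, 571 and 689 CPM, F13a1 at 369, 375 and 456 CPM and Ly6c2 at 962, 414 and 468 CPM. It was also 4.62 times lower in classical monocytes, of which the NVC library held 97 cells, too few for the minimum of 100, so that this value was chosen after it was seen. Thbs1 was higher in capillary endothelial cells (119 against 35.3 CPM), interstitial macrophages (213 against 96.8 CPM) and alveolar macrophages (2.77 times [1.99 to 3.94], 1.87 to 6.34 over the alternatives). The alveolar macrophage levels were 44.5 CPM in ARDS and 16.1 CPM in NVC, where free RNA gives 31.2 and 14.0 CPM. Pericytes or smooth muscle cells had 955 against 539 CPM and fibroblasts 1915 against 1820 CPM, but these ratios were under 1 with each cell weighted alike (0.952) and at resolution 0.8 (0.938). Fibroblasts held 51.5% of the Thbs1 UMIs of the NVC library and 24.0% of those of the ARDS library, in which neutrophils held 31.1% and classical monocytes 27.7%. Of all UMIs, neutrophils held 6335080 of 54589488 in the ARDS and 553463 of 35003365 in the NVC library, and classical monocytes 10569273 and 588043. The Thbs1 ratio of 1.46 over all cells thus also reflects the makeup of the cells. The part due to makeup was not computed for this comparison.

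Cd36 and Cd47 encode receptors of thrombospondin-1. Cd36 was lower in ARDS than in NVC cells over all cells (94.9 against 503 CPM) and in neutrophils (11.2 against 179 CPM), interstitial macrophages (9.64 times) and capillary endothelial cells (1.56 times). Capillary endothelial cells held 12960 of the 17611 Cd36 UMIs of the NVC library and were 2.70 times lower in share in the ARDS library. The value of Cd36 over all cells thus also reflects the smaller share of this class. Cd47 was 1.24 times higher over all cells [1.22 to 1.27] and 3.05 times higher in neutrophils, the highest of the 11 classes (lowest 1.075 in fibroblasts). The list of thrombospondins and their binding partners had medians between -0.24 and 0.32, none among the outer 2.5% of random lists on either side in the 11 classes. The median log2 ratio over genes was -0.63 in neutrophils and -0.49 over all cells, and between -0.23 and 0.19 in the other classes. Scaling to that median raises the ratios of neutrophils and of all cells, and Thbs1 over all ARDS cells is then 2.05 times higher.

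**Figure D2:**
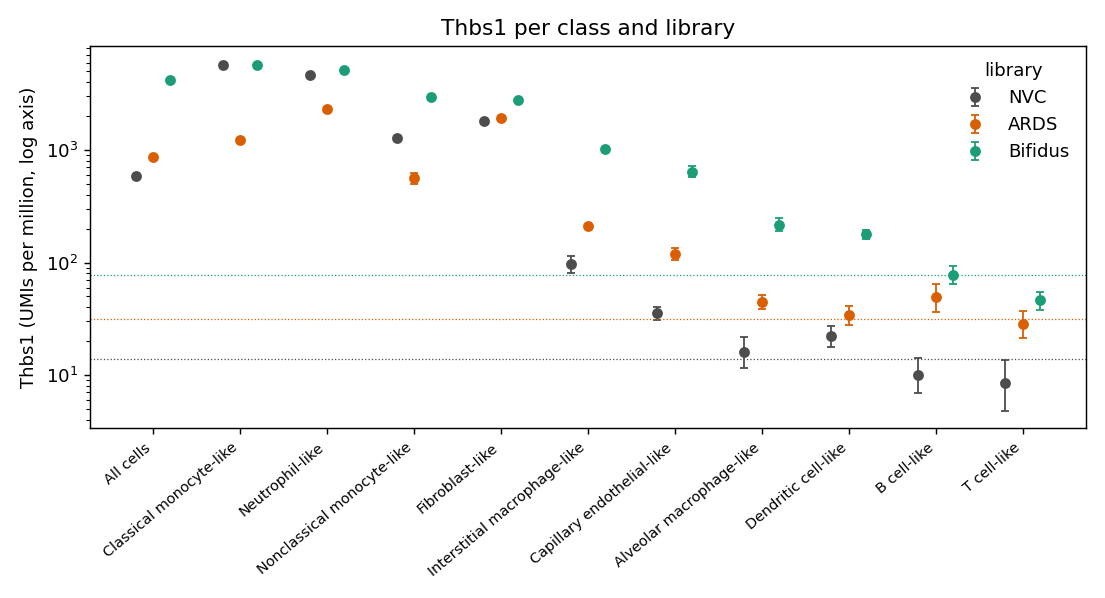
Thbs1 level (CPM, log axis) over all cells and per class in the NVC, ARDS and Bifidus libraries; bars are exact 95% Poisson intervals and dotted lines mark the level that free RNA gives in each library (14.0, 31.2 and 77.7). Classical monocytes stood at 5710, 1237 and 5676 and T cells at 8.45, 28.4 and 46.0.

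Bifidus against ARDS asks how the lung labelled Bifidus differed from the ARDS lung. Immune cells were 79.2% of Bifidus cells and 64.9% of ARDS cells. Non-immune cells were 6.34% [5.83 to 6.87] against 25.1% [24.3 to 26.0], 3.97 times lower [3.62 to 4.36]. Capillary endothelial cells were 5.29 times lower [4.52 to 6.21] (a ratio of 0.189, 0.171 to 0.298 over the alternatives), fibroblasts 3.07 times lower [2.70 to 3.50] and pericytes or smooth muscle cells 8.09 times lower, on 23 Bifidus cells (a ratio of 0.124, 0.0475 to 0.162). Within non-immune cells alone, fibroblasts were 1.29 times higher [1.13 to 1.47] and capillary endothelial cells 1.33 times lower. The 6 AT2 cells and 7 AT1 cells of the Bifidus library allow no comparison of levels. Neutrophils were 27.6% against 23.9% of cells, but within immune cells their share ratio was 0.947 [0.895 to 1.00], and over all cells it was 0.481 with a floor per library and 2.10 with each library clustered alone. T cells (1.72 times), B cells (1.74 times) and NK cells (1.83 times) were higher, and alveolar macrophages were 2.06 times lower. The T cell class leaves out the unnamed cluster 20, which scored highest for T cell markers. It held 89 Bifidus and 169 ARDS cells, so counting it would lower the T cell ratio.

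Monocytes and macrophages were divided differently. Classical monocytes were 24.7% of Bifidus and 11.5% of ARDS cells (2.15 times higher [2.00 to 2.31]), and interstitial macrophages 1.84% against 10.7% (5.80 times lower [4.91 to 6.89]). When each library was clustered alone, the first ratio became 0.935 and the second 1.28, so neither direction holds for that choice. As 1 set, chosen after these values were seen, both classes were 26.6% of Bifidus and 22.2% of ARDS cells, and the ratio of 1.20 became 0.985 with each library alone. Bifidus classical monocytes came from cluster 1 (94.4%) and ARDS ones from cluster 5 (98.3%). Bifidus interstitial macrophages were cluster 7 (64.2%) and cluster 26 (35.8%), and ARDS ones cluster 7 (95.5%). Neutrophils were mostly cluster 2 in the Bifidus library (74.5%) and clusters 3 and 6 in the ARDS library. Fibroblasts were clusters 18 and 16 against 16 and 29, and alveolar macrophages clusters 17 against 24, so levels per class again compare members that cluster apart.

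Thbs1 was 4191 CPM over all Bifidus cells [4175 to 4208] and 864 CPM over all ARDS cells [856 to 872], 4.85 times higher [4.80 to 4.90] (3.17 with the mean of cells). Classical monocytes stood at 5676 against 1237 CPM (4.59 times [4.51 to 4.67]), nonclassical monocytes at 2980 against 560.0 CPM (5.32 times [4.77 to 5.95], 4.53 to 9.58 over the alternatives, in a class that carries classical monocyte genes) and neutrophils at 5185 against 2316 CPM (2.24 times [2.19 to 2.29]). Interstitial macrophages (1022 against 213 CPM), capillary endothelial cells (643 against 119 CPM) and dendritic cells (179 against 34.0 CPM) were 4.80 times (3.78 to 12.2 over the alternatives), 5.38 times (2.79 to 6.41) and 5.25 times (4.52 to 35.8) higher, and fibroblasts 1.45 times (1.36 to 1.77); the ARDS dendritic level is near that of free RNA (31.2 CPM). Alveolar macrophages had 218 against 44.5 CPM, 4.89 times higher (3.11 to 18.6), on the same ARDS level of free RNA. Within the 8 clusters, other than those of lymphocytes, that hold at least 100 cells of each library, the ratio was 1.22 in neutrophil cluster 3, 1.84 in classical monocyte cluster 5 and in capillary cluster 10, 2.86 and 2.08 in fibroblast clusters 16 and 18, and up to 8.86 in dendritic cluster 12. The clusters of neutrophils and classical monocytes among these held 2.10% of the Thbs1 UMIs of the Bifidus library. Classical monocytes held 62.3% of the Thbs1 UMIs of the Bifidus library, and cluster 9, which has no class, held 21.7%.

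Among cells with at least 1000 UMIs, thinned to that number, 65.6% of Bifidus cells [64.6 to 66.7] had a Thbs1 UMI, against 35.2% of ARDS cells and 16.6% of NVC cells. Cells with fewer UMIs, 772 Bifidus, 1580 ARDS and 2016 NVC cells, were left out of these shares. T cells, which should lack the gene, had a UMI in 3.85%, 2.96% and 1.62% of cells thinned in the same way. Their median depths before thinning were 3943, 3736 and 3363 UMIs, against 4174, 2946 and 2308 for all cells. Thbs1 in T cells (46.0 CPM in Bifidus) lay under and in B cells (77.6 CPM) at the level that free RNA gives (77.7 CPM); ARDS B cells, at 48.9 CPM, were above theirs (31.2 CPM). Cd47 was lower over all Bifidus cells (329 against 475 CPM, 1.44 times), in classical monocytes (1.47 times) and in neutrophils (1.55 times), with ratios from 0.644 to 1.004 over the 11 classes. Cd36 was 3.06 times lower over all Bifidus cells (31.0 against 94.9 CPM), 2.62 times lower in neutrophils and 2.24 times lower in fibroblasts, and 1.89 times higher in alveolar macrophages [1.66 to 2.16] and 1.62 times in nonclassical monocytes [1.10 to 2.44]. In capillary endothelial cells, which held 2907 of the 5179 Cd36 UMIs of the ARDS library and were 5.29 times lower in share, the level was 1055 against 1146 CPM (ratio 0.920 [0.834 to 1.01]). In interstitial macrophages it was 3.84 times higher, but within cluster 7 the ratio was 0.599 [0.295 to 1.09]. The list of thrombospondins and their binding partners had a median of -0.62 in neutrophils and between -0.12 and 0.31 in the other classes.

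Interferon-stimulated genes were lower in Bifidus cells in each of the 11 classes compared, from -0.19 in interstitial macrophages (percentile 5.01; 0.23 within cluster 7) to -1.91 in fibroblasts. Gbp2 was 456 against 1577 CPM in neutrophils and 87.5 against 634 CPM in classical monocytes. Oasl1 was 34.9 against 279 CPM in nonclassical monocytes. Cytokine and chemokine genes had medians of -1.80 in classical monocytes, -1.24 in alveolar macrophages, -0.62 in neutrophils, -0.57 in nonclassical monocytes (-1.31 to -0.24 over the alternatives) and 0.04 in interstitial macrophages (-0.21 with each cell weighted alike, -0.41 within cluster 7). In classical monocytes Il10 (27.5 times), Ccl5 (16.4 times) and Tnf (54.0 against 807 CPM) were the lowest. Cxcl10 was 662 against 3769 CPM and Cxcl1 59.8 against 399.8 CPM in neutrophils, where Cxcl9 (14.6 times), Tagap (11.7 times) and Tifa (9.21 times) were lowest. NF-kB feedback and target genes had medians from -0.87 in neutrophils to -0.18 in capillary endothelial cells (0.03 with a floor of 1000 UMIs), and Icam1 in neutrophils was 345 against 1687 CPM.

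**Figure D3:**
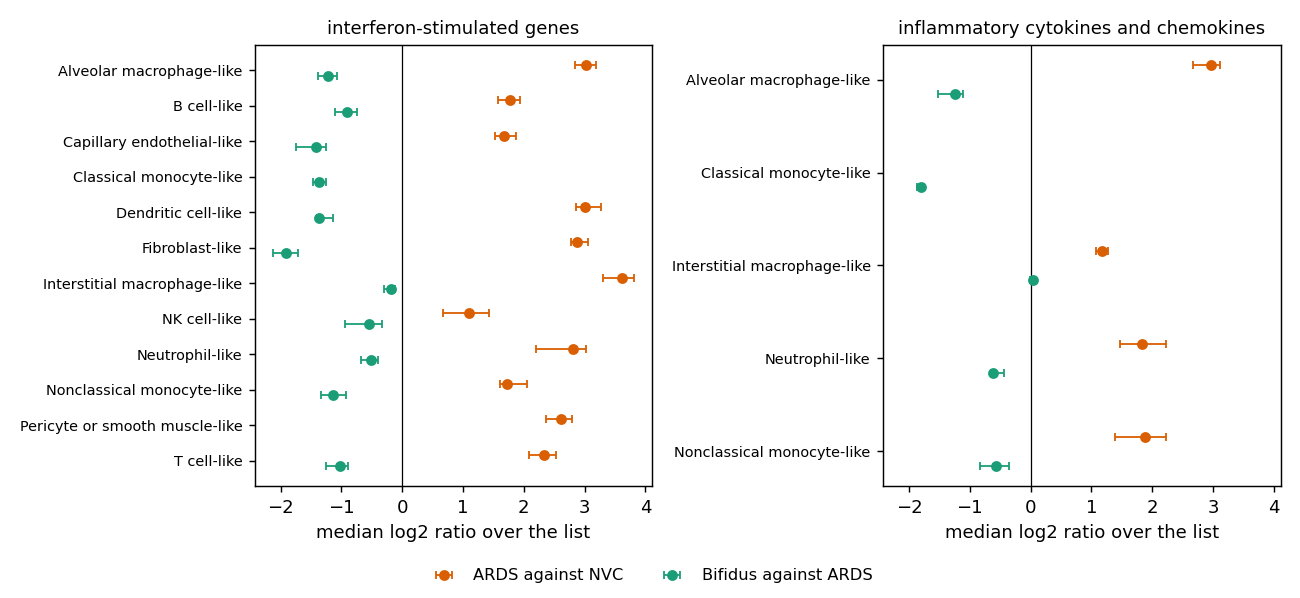
Median log2 ratio over the interferon-stimulated genes (left) and the cytokine and chemokine genes (right) per class for ARDS against NVC and for Bifidus against ARDS; bars are 95% counting intervals. The interferon medians ran from 1.10 to 3.62 for ARDS against NVC and from -1.91 to -0.19 for Bifidus against ARDS.

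Glycolysis and cell cycle genes were higher in Bifidus than in ARDS classical monocytes, though not in all classes. Srxn1 (7.61 times), Mxi1 (7.11 times) and Basp1 (5.69 times) had the highest ratios in classical monocytes, and Hmox1, the heme oxygenase gene, stood at 1897 against 471 CPM. Cell cycle genes had medians of 1.17 in classical monocytes (0.96 to 1.54 over the alternatives), with Ube2c at 91.7 against 1.89 CPM, and of 1.30 in nonclassical ones (0.53 to 1.77). They lay among the lowest 2.5% of random lists in dendritic cells (-0.37), neutrophils (-0.23) and T cells (-0.19). The glycolysis list had medians of 0.62 in classical monocytes and 0.72 in neutrophils, and lay among the lowest 2.5% of random lists in T cells (-0.23), fibroblasts (-0.32), alveolar macrophages (-0.31) and B cells (-0.13). Of these 4 medians only that of T cells kept its sign under all alternatives; the others reached 0.02, 0.26 and 0.01. In nonclassical monocytes Retnla (268 against 1.55 CPM; 1 ARDS UMI, ratio 173 [30.8 to 6861]), Thbs1 and Pde3b (3.51 times) were highest, and Cxcl9 (0.969 against 102 CPM; 1 Bifidus UMI, 106 times lower [18.3 to 4234]), Gbp4 (17.3 times) and Retnlg (15.6 times) lowest. In neutrophils Dusp6 (6.77 times), Arrdc3 (5.90 times) and Mindy1 (5.27 times) were highest, and the granule and migration list had a median of 0.53. Antioxidant genes had a median of 0.85 in capillary endothelial cells and were lower in T cells (-0.41), B cells (-0.37) and NK cells (-0.32).

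Macrophages, stromal cells and lymphocytes differed too. The clearance list had a median of 0.73 in interstitial macrophages, in which Retnla was 893 against 3.23 CPM and Cd163 8.57 times higher, but this went with the larger part from cluster 26. Within cluster 7 (102 Bifidus and 1070 ARDS cells) the clearance median was 0.05 [-0.08 to 0.22], the Retnla ratio 1.11 [0.217 to 3.53] and the Cd163 ratio 2.03 [0.383 to 6.96], on 3 Bifidus UMIs each. The clearance list had medians of 0.47 in alveolar macrophages and 0.06 in classical monocytes. MHC class II genes were higher in interstitial macrophages (0.65, and 0.67 within cluster 7), dendritic cells (0.53) and B cells (0.42), with -0.21 in alveolar macrophages (0.29 with no doublets left out) and 0.03 in capillary endothelial cells. The endothelial activation list had a median of -0.52 (Lcn2 73.6 against 615 CPM), the junction list one of 0.07 (-0.10 with the median of ratios) and the matrix list in fibroblasts one of 0.04 (-0.23 with each cell weighted alike). Inflammasome genes had medians of -0.48 in nonclassical and -0.24 in classical monocytes. T and NK cell activation genes had medians of -0.52 and -0.62, and Ifng in NK cells was 534 against 5417 CPM. In T cells S1pr1 (2.42 times), Elovl6 (2.39 times) and Trib2 (2.05 times) were highest and Id3 (15.3 against 138 CPM), Cxcl10 (7.49 times) and Hspa1a (6.65 times) lowest. In B cells Timm13 (2.83 times), Crip1 (2.73 times) and Vim (2.61 times) were highest and Hspa1a (9.61 times), Phlda1 (8.74 times) and Hspa1b (7.88 times) lowest; the B cell list had a median of -0.03. Immediate early and heat shock genes had medians of -1.13 in B cells and -0.74 in T cells and of 0.89 in fibroblasts. The median log2 ratio over genes lay within 0.19 of 0 in each class.

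Bifidus against NVC asks which levels of the Bifidus lung also differed from the NVC lung. Neutrophils were 7.90 times higher in share [7.07 to 8.85] (4.67 with a floor per library), classical monocytes 26.2 times higher [21.4 to 32.4] (8.27 with each library clustered alone) and capillary endothelial cells 14.3 times lower [12.3 to 16.7] (a ratio of 0.0700, 0.0348 to 0.0994 over the alternatives). Thbs1 was 7.08 times higher over all cells [6.98 to 7.18]. In neutrophils it was 1.11 times higher (5185 against 4662 CPM), in nonclassical monocytes 2.33 times (1.35 to 5.46 over the alternatives), in fibroblasts 1.53 times (1.45 to 2.03) and in interstitial macrophages 10.6 times (8.35 to 22.8). The ratio was 18.2 in capillary endothelial cells [15.3 to 21.6] (7.33 to 26.4), 13.5 in alveolar macrophages [9.73 to 19.2] (10.55 to 66.5) and 8.10 in dendritic cells [6.48 to 10.2] (4.65 to 38.7). The NVC levels of alveolar macrophages and dendritic cells were 16.1 and 22.1 CPM, where free RNA gives 14.0 CPM. Classical monocytes had 5676 against 5710 CPM, but held 26540825 of the 57697971 Bifidus UMIs and only 588043 of the 35003365 NVC UMIs. The Thbs1 ratio of 7.08 over all cells thus also reflects the makeup of the cells. The part due to makeup was not computed for this comparison. Interstitial macrophages came mostly from cluster 7 in the Bifidus and cluster 26 in the NVC library. The main clusters also differed in capillary endothelial cells (10 against 4) and fibroblasts (18 against 15). The levels of these 3 classes thus compare members that cluster apart. Interferon-stimulated genes had higher medians in 9 of 10 classes, up to 3.24 in interstitial macrophages, and one of -0.01 in capillary endothelial cells. The cytokine list was higher in the 4 classes compared (0.79 to 1.88). MHC class II genes had medians of -1.35 in capillary endothelial cells and -0.71 in interstitial macrophages. Immediate early and heat shock genes were lower in each of the 10 classes, from -0.11 in fibroblasts (percentile 12.6) to -0.90 in B cells. Cd36 was 16.2 times lower over all cells, 1.70 times lower in capillary endothelial cells [1.55 to 1.86], 41.8 times lower in neutrophils and 1.32 times higher in alveolar macrophages [1.15 to 1.51]. Capillary endothelial cells held 12960 of the 17611 Cd36 UMIs of the NVC library, so the value over all cells also reflects their lower share. Cd47 was 1.16 times lower over all cells, with ratios from 0.998 to 1.97 over the 10 classes.

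ARDS against NVC and Bifidus against ARDS share the ARDS library, and opposite signs arise from that alone. Of 87 pairs of list and class measured in both comparisons, 62 (71.3%) had opposite signs, 38 of them higher and then lower. With the ARDS cells split at random into 2 parts, 1 per comparison, 61 did (70.1%). In 20 simulations of libraries that differed by counting error alone, 58.0% did. These hold no variation between libraries, so they cannot show whether 71.3% is more than such variation gives. The split removes shared counting error but not what the ARDS library has of its own.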

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

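The 6 tests of the Thbs1 pattern in this part, and the sets of classes they cover, were chosen only after the result was seen. Thbs1 over all cells was 4191 CPM in the Bifidus and 864 CPM in the ARDS library. The tests argue against free RNA, since Thbs1 in Bifidus T cells was 1.10% of its level over all cells. They argue against the makeup of the classes as the whole source, since ARDS levels per class at the Bifidus makeup give a ratio of 1.24 where 4.85 was seen. Other clusters within a class are argued against in interstitial macrophages, dendritic cells and fibroblasts. There 4 shared clusters gave a pooled ratio of 2.86 [2.75 to 2.96] against 1.76 by class, so the clusters do shift the class ratio. Fibroblast clusters 16 and 18 weigh most, with 3508 and 1882 Bifidus Thbs1 UMIs, against 966 in macrophage cluster 7 and 499 in dendritic cluster 12. The ratios of clusters 7 and 12 alone were 4.57 and 8.86. These 4 clusters hold 2.83% of the Thbs1 UMIs of the Bifidus library. In neutrophils and classical monocytes other clusters may be a large part: 2 shared clusters gave 1.49 [1.45 to 1.54] against 3.99 by class, and held only 2.88% of the Bifidus Thbs1 UMIs of both classes, so this cannot be told apart from a change of level. Nor can it in capillary endothelial cells, where 1 shared cluster gave 1.84 [1.42 to 2.36] against 5.38 by class and held 25.9% of their Bifidus Thbs1 UMIs.

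Nonclassical monocytes may hold classical ones, which cannot be told apart from a change of level either. Over 14 genes high in cluster 1 the median share of classical RNA in Bifidus nonclassical cells was 0.222 where Thbs1 would need 0.458, with ARDS cells as baseline. With NVC cells as baseline it was 0.417, over 37 genes, where 0.373 is needed. Of 36 choices of source cluster (1 or 9), baseline and gene bounds, 13 argued against such a mixture, 10 for it and 13 for neither. All of the choices against it used the ARDS baseline, and all of those for it the NVC baseline. The outcome thus turns on the baseline, and ARDS is the library that the Thbs1 pattern compares with. A biological explanation of the Thbs1 pattern stays open as untested, since the group is confounded with the animal and the preparation.

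Thbs1 went in opposite directions in cell classes of ARDS against NVC: the ratio was 3.38 in capillary endothelial cells and 0.438 in nonclassical monocytes, the latter from 0.221 with a floor per library to 0.915 with seed 1. This difference between classes was not tested. The list of immediate early and heat shock genes had a median of 0.89 in fibroblasts and -1.13 in B cells for Bifidus against ARDS, and that difference between classes was not tested.

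Cluster 9 has no class and so enters no comparison of classes, yet its 1018 Bifidus cells carried Thbs1 at 4789 CPM. It is named here because those cells would otherwise be left out.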

How the results depend on the processing

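Naming without the free RNA rule, cluster 9 with the classical monocytes, and leaving out small clusters of 1 library were chosen only after the results were seen. No paired analysis was possible because each group has 1 library, so the groups share only replicate number 1. Depth limits the share of cells with a Thbs1 UMI, from which 2016 NVC, 1580 ARDS and 772 Bifidus cells under 1000 UMIs were left out; AT1 and AT2 cells are limited by cell number. Of 8361 values of the other results under alternatives set beforehand, 7170 stayed within the counting interval and 1186 moved outside it. The remaining 5 changed direction where the result had passed a size bound: a share ratio or list median of at least 1.5 times with an interval clear of no difference (lists also beyond random ones), or a gene ratio of at least 2 times with an interval beyond 1.5. Whatever the size, 179 values of 90 results out of 884 lay on the other side of no difference. Of 60 share ratios, 278 list medians and 561 gene ratios, 32, 29 and 200 moved by over 1.5 times under some alternative, so the size of these is less certain than their counting intervals. Thbs1 ran from 0.348 to 5.68 in dendritic cells and from 0.221 to 0.915 in nonclassical monocytes of ARDS against NVC, and from 0.110 to 1.78 in B cells of Bifidus against ARDS. The interferon medians kept their sign in all 11 classes and all alternatives for ARDS against NVC and for Bifidus against ARDS, but within cluster 7 that of interstitial macrophages was 0.23 for the latter. Each library clustered alone gives shares only, without levels. The cause of the shifts below was not tested unless stated.

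With a floor of 1000 UMIs, 8253 NVC, 8913 ARDS and 7862 Bifidus cells were kept. For ARDS against NVC the neutrophil share ratio was 8.01, that of non-immune cells 0.430 and Thbs1 over all cells 1.42. For Bifidus against ARDS, monocytes with interstitial macrophages had 1.12 and Thbs1 4.96. With a floor per library, 6616, 5304 and 5081 cells were kept. The share ratios for ARDS against NVC were 9.72 for neutrophils, 0.365 for non-immune cells and 9.20 for monocytes with interstitial macrophages. For Bifidus against ARDS they were 1.88 for classical monocytes, 0.136 for interstitial macrophages, 0.322 for non-immune cells and 1.05 for monocytes with interstitial macrophages. Thbs1 over all cells had 1.35, 5.54 and 7.45 for ARDS against NVC, Bifidus against ARDS and Bifidus against NVC. Cytokine genes in neutrophils had -0.75 and interferon genes -0.87 for Bifidus against ARDS, and Pfkfb3 in nonclassical monocytes reversed to 0.659 for ARDS against NVC. With at most 5% mitochondrial UMIs, 8452, 9531 and 8234 cells were kept, and Thbs1 had 1.43 for ARDS against NVC and 6.95 for Bifidus against NVC. With no doublets left out, 10943, 11166 and 9197 cells were kept. The non-immune ratio for Bifidus against ARDS was then 0.286, and H2-Ab1 in alveolar macrophages reversed to 1.12.

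At resolution 0.8 the share ratio of classical monocytes was 9.36 for ARDS against NVC and 2.98 for Bifidus against ARDS. For the latter comparison interstitial macrophages had 0.371 and both classes as 1 set 1.72. With seed 1, classical monocytes had 5.63 and 3.13, both classes 5.17 and 1.73, and non-immune cells 0.450 for ARDS against NVC. The cell cycle list in nonclassical monocytes reversed to -0.0298 for Bifidus against NVC. With each library alone, classical monocytes had 8.85 for ARDS against NVC and reversed to 0.935 for Bifidus against ARDS, and interstitial macrophages reversed to 1.28. Neutrophils had 3.32 for ARDS against NVC, non-immune cells 0.516 and 0.292, and monocytes with interstitial macrophages 4.603 and 0.985. With cluster 9 among the classical monocytes the share ratios were 9.36 and 3.15, and 1.72 for both classes in Bifidus against ARDS; the added cells give this shift. Without small clusters of 1 library, neutrophils had 8.21 and non-immune cells 0.446 for ARDS against NVC.

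With the mean of cells, Thbs1 over all cells had 2.01, 3.17 and 6.36 in the 3 comparisons, and with the median of ratios 2.05, 5.30 and 10.4. The latter scaling gave 2.31 for cytokine and 3.23 for interferon genes in neutrophils of ARDS against NVC, and -0.67 for cytokine genes of Bifidus against ARDS. With free RNA taken off, Thbs1 had 4.94 for Bifidus against ARDS, Cd36 in fibroblasts reversed to 1.23 for Bifidus against NVC, and Ccl3 in T cells to 0.405 for ARDS against NVC. With 1 CPM added, interferon genes in neutrophils had -0.75 for Bifidus against ARDS. Without thinning, 21.5% of NVC, 49.5% of ARDS and 72.1% of Bifidus cells had a Thbs1 UMI.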

Other observations

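The tests of dilution and of heat shock in this part were chosen only after the results were seen; the test of broken cells was written before. Cluster 9 held 1057 cells, of which 1018 came from the Bifidus library, so it may be that library rather than a cell type; counting it with the classical monocytes gives a share ratio of 3.15 for Bifidus against ARDS. Its levels differed from those of Bifidus cells in cluster 1, the main cluster of classical monocytes, and in cluster 11, the nonclassical monocytes. Lgmn, a lysosomal protease gene, stood at 1030 CPM in cluster 9, 386 CPM in cluster 1 and 512 CPM in cluster 11, and C1qa at 438, 8.25 and 25.2 CPM. Csf1r was 590, 326 and 515 CPM, and F13a1 307, 1015 and 456 CPM. Ccr2 stood at 363, 484.5 and 549 CPM and Vcan at 391, 929 and 689 CPM, so that cluster 11 carries classical monocyte genes as well.

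Heat shock genes were highest in lymphocytes of the ARDS library. Hspa1a in B cells was 2063 CPM in NVC, 6090 CPM in ARDS and 634 CPM in Bifidus, and in T cells 1275, 2951 and 443 CPM. Free RNA does not reach this level, since it would give 0.427% of Hspa1a in ARDS B cells. A general response to cell handling is not what the immediate early genes show for ARDS against NVC. The median log2 ratio of 13 of them was 0.000571 in B, T and NK cells (quartiles -0.18 and 0.36), against 0.61 for the heat shock genes. The gap between ARDS and Bifidus was not tested in this way. In B cells Jun stood at 1490 CPM in ARDS and 574 CPM in Bifidus and Egr1 at 187 and 93.4 CPM. Fos stood at 603 and 577.5 CPM, so handling stays open for that gap. A heat shock response limited to 1 preparation, or one of the lungs, may remain; neither was tested.

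Non-immune cells were a smaller share of the Bifidus than of the ARDS library. Dilution by myeloid cells alone is argued against, since there were 0.145 times as many non-immune cells per lymphocyte [0.127 to 0.164]. Cells broken after release could not be excluded: 70 markers of capillary endothelial cells and fibroblasts stood in free RNA at 0.511 times their ARDS level [0.460 to 0.548], between the bounds set for either reading. For ARDS against NVC the number per lymphocyte was not computed. Non-immune cells and lymphocytes had share ratios of 0.480 and 0.4275, so a lower total from dilution is not argued against. Dilution alone is argued against for the makeup of the non-immune cells, by 2.06 times as many fibroblasts per capillary endothelial cell [1.86 to 2.29]. Dilution leaves that number unchanged. Its lowest value under the alternatives was 1.65 [1.48 to 1.84], and that of fibroblasts per AT2 cell 2.09 [1.34 to 3.35], so a difference above 1.5 times does not hold throughout. A lower yield of non-immune cells in 1 preparation and a loss in the lung cannot be told apart with 1 library per group, and a biological explanation stays open as untested.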
